A study of Mus musculus with 8 samples.

How the data were processed

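RNA sequencing of mouse dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, was re-analysed from the deposited count files of 8 libraries. The inducible knockout mice (iKO) carried floxed alleles of Ehmt2, which encodes the histone methyltransferase G9a, and an inducible Cre recombinase driven by the sensory neuron gene Avil. The wild-type mice (WT) were littermates without Cre, and whether they carried floxed alleles was not stated. Mice of both genotypes received vehicle or complete Freund's adjuvant (CFA), an inflammatory agent, in the left paw, and tissue was collected 14 days later. The 4 groups held 2 libraries each. Per the submitters' processing notes, total RNA was extracted with an RNeasy kit and sequenced on an Illumina instrument, and the authors aligned the reads with HISAT2 2.2.1 to the mouse assembly GRCm39 (mm39), handled them with SAMtools 1.19.2 and counted reads per gene with featureCounts 2.0.6. The notes name DESeq2 for the later test without a version. The gene annotation, the strand setting, the read length and the layout of the reads were not stated, nor were the dose, the age or sex of the mice, the side and the spinal levels of the ganglia, or whether each library came from a separate animal.

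The deposited values were counts, whole numbers of reads per gene symbol, as the authors' read counter gave them, with no scaling for depth or gene length. Each of the 8 files held 25780 genes with identical symbols in identical order, no file held values of another sample (0 further columns), and 0 genes lacked a read in every library. Because the files give symbols only, no genome positions are reported.

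Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few reads were removed with filterByExpr, which left 20235 genes holding at least 99.9% of the reads of every library. Library sizes were scaled by the trimmed mean of M values (TMM), and CPM, the depth-scaled counts given below, use these scaled sizes. One quasi-likelihood negative binomial model with a mean for each group was fitted to all 8 libraries, so the 4 groups shared 1 estimate of the spread (common dispersion 0.0753, prior degrees of freedom 4.68). Two-sided quasi-likelihood F-tests were made for CFA against vehicle in WT, CFA against vehicle in iKO, iKO against WT under vehicle, iKO against WT under CFA, the difference between both CFA responses (the interaction), iKO against WT averaged over treatments and CFA against vehicle averaged over genotypes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, with a threshold of 0.05. Log2 fold changes are given ± their standard error, and CPM as mean ± SD of n = 2 libraries per group. The p-values measure the spread between these libraries, since separate animals are not stated.

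The groups, comparisons, tests, gene lists, naming rule and the first set of alternatives were fixed before the data were examined. The test was fixed as the default quasi-likelihood fit, with legacy = TRUE listed as an alternative to it. That setting proved to be the default of the installed version, and this was found only after counts under both settings had been seen, so legacy = FALSE was added as an alternative at that point. Ehmt2, Trpa1 and Trpv1 were named in every comparison. In each comparison of single groups the rule named the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold that had a mean log2 CPM of at least 1 and both libraries of one group above both of the other. Where fewer passed, all were named, and where 0 passed, the 3 with the smallest p. The interaction used the same rule without the separation. Gene models without an established name were counted but not named. In each list the 4 members with the smallest p in a comparison could be named. Genes named outside this rule are said to have been chosen after their values were seen.

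The 43 lists were Transduction channels, Sodium channels, Potassium channels, Calcium channels, Opioid and cannabinoid system, Glutamate and GABA receptors, Neuropeptides, Peptidergic nociceptors, Non-peptidergic nociceptors, C-LTMR (C-fibre low-threshold mechanoreceptors), Large myelinated neurons, Pan-neuronal, Nerve injury response, Immediate early genes, Heat shock and unfolded protein response, Macrophage, Lymphocyte, Neutrophil and mast cell, Cytokines and chemokines, Interferon response, Satellite glia, Myelinating Schwann cell, Non-myelinating Schwann cell, Sterol synthesis, Fibroblast and extracellular matrix, Endothelium, Pericyte and smooth muscle, Erythroid, Skeletal muscle, Adipocyte, Spinal cord, Bone and cartilage, H3K9 methylation machinery, H3K4 and H3K27 machinery, Germline genes, Clustered protocadherins, Imprinted genes, Avil neighbours, Ehmt2 neighbours, Sex-linked, Mitochondrial transcripts (26 symbols under both naming systems, 13 of them in the files), Respiratory chain and Ribosomal proteins. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 43 lists within a comparison. Camera with an estimated correlation and fry were run beside it. Member counts are given over all genes and "adjusted over the list alone", that is, with the adjustment made within the list.

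Where a group had 0 reads of a gene, its fold is a lower bound against a floor of 3 reads over the group. With 1 to 3 reads the ratio of scaled counts is given with an exact 95% interval. Fitted fold changes of such genes depend on the prior count and are no bound. Intervals and floors cover counting error only, because reads made by amplification without molecular identifiers are not independent molecules.

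In simulated data CFA in WT recovered 17.9%, 85.1% and 98.5% of genes changed 2-, 4- and 8-fold. CFA in iKO recovered 19.4%, 89.6% and 100%, and iKO under vehicle 22.4%, 82.1% and 100%. IKO under CFA recovered 16.4%, 88.1% and 97.0%, and the interaction 0%, 55.2% and 87.9%. Each called 2 to 9 unchanged genes. These rates may not hold at the unequal spread here. Alternatives were size factors by the median of ratios (RLE), no filter, at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, robust and legacy settings of the quasi-likelihood fit, only the groups compared, the replicate number as a block, and each library left out in turn. Further alternatives were added after seeing the data and are named as such, and the patterns weighed in the closing section were chosen from the results. Mouse RefSeq and GENCODE annotations of the earlier assembly served only for gene order around Ehmt2 and for transcript length and GC content. Sequence reads, alleles, isoforms and histone marks were not analysed here. Results of some genes are not reported here.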

Results

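Reads from dorsal root ganglia were counted for 25780 gene symbols in 8 libraries, 2 from each of 4 groups of mice. Wild-type (WT) mice and mice with an inducible deletion of G9a in sensory neurons (iKO) received vehicle or CFA, which inflames the injected paw, 14 days before collection. The WT vehicle libraries 1 and 2 held 26312614 and 29763833 reads, and the WT CFA libraries held 41617192 and 32176987. The iKO vehicle libraries held 42971823 and 36161344 reads, and the iKO CFA libraries held 32694935 and 35516017. Values below are CPM as mean ± SD or log2 fold changes ± standard error, with n = 2 libraries per group.

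Libraries of the same group differed in which tissue genes they held, and the WT vehicle libraries stood apart from all others. The nuclear noncoding RNA Malat1 was at 1323 and 1187 CPM in WT vehicle and between 27.4 and 57.0 CPM in the 6 other libraries. Meg3, an imprinted noncoding RNA, was at 877 and 1098 CPM there and between 3.59 and 16.8 CPM elsewhere, and Fos, a transcription factor induced within minutes by activity or handling, was at 99.1 and 91.9 CPM against 3.01 to 5.87 CPM. Jchain, the joining chain of antibodies, was at 1944 and 780.1 CPM in WT vehicle and at 0.445 to 31.5 CPM elsewhere. WT CFA library 2 held more red cell, granulocyte and mitochondrial RNA than WT CFA library 1. Hbb-bs, a haemoglobin chain, was at 752 against 79.7 CPM, and S100a8, a granulocyte protein, at 57.7 against 5.55 CPM. Mitochondrial coding genes took 12.1% of the reads in WT CFA library 2 and 3.94% in WT CFA library 1, against 3.57% and 2.76% in WT vehicle, 1.34% and 1.86% in iKO vehicle and 6.09% and 5.95% in iKO CFA. The median difference between the libraries of a group was 0.59 on the log2 scale for WT CFA, against 0.28 for WT vehicle, 0.17 for iKO vehicle and 0.20 for iKO CFA.

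**Figure D1:**
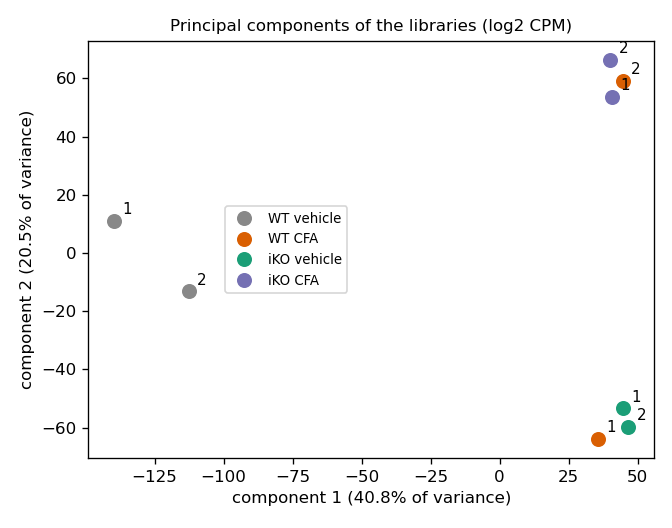
Principal components of the 8 libraries from log2 CPM, with component 1 (40.8% of the variance) on the horizontal axis, component 2 (20.5%) on the vertical axis and each point a library coloured by group. The WT vehicle libraries lie at -140 and -113 on component 1 and the other 6 between 35.5 and 46.7, while on component 2 WT CFA library 1 (-63.9) lies beside iKO vehicle (-53.3 and -59.7) and WT CFA library 2 (59.1) beside iKO CFA (53.7 and 66.3). On component 3 (18.8%) both WT CFA libraries (-56.9 and -100.3) lie apart from the iKO libraries (27.8 to 50.5).

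Ehmt2, the gene floxed in iKO that encodes the histone H3 lysine 9 methyltransferase G9a, was at 74.4 and 65.4 CPM in WT vehicle, 74.2 and 61.3 CPM in WT CFA, 33.998 and 31.6 CPM in iKO vehicle and 45.0 and 44.2 CPM in iKO CFA. It was lower in iKO than in WT under vehicle (log2 fold change -1.09 ± 0.18, adjusted p = 0.00655) and averaged over treatments (-0.85 ± 0.12, adjusted p = 0.00718). Under CFA the difference was -0.60 ± 0.18 and did not pass (adjusted p = 0.154). The vehicle call was lost without WT vehicle library 1 (adjusted p = 0.0561) or iKO vehicle library 1 (0.0699) or 2 (0.0935), and the averaged call without iKO CFA library 1 (0.0543) or iKO vehicle library 1 (0.0557) or 2 (0.0646). The CFA difference passed without WT CFA library 2 (-0.74, adjusted p = 0.00377) and in DESeq2 (-0.61, 0.0205). With CFA Ehmt2 changed by -0.04 ± 0.17 in WT (adjusted p = 0.891) and 0.44 ± 0.18 in iKO (0.147), with an interaction of 0.49 ± 0.25 (0.214). The change in iKO passed as higher without WT CFA library 1 (0.0150), 2 (0.0151) or both (0.0154) and with the iKO libraries alone (0.47, 0.00282), and the interaction without WT CFA library 1 (0.63, 0.0355).

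The channels named in the title of the series were also followed in every comparison. Trpa1, an irritant-gated channel of nociceptors, was at 49.4 ± 12.3 CPM in WT vehicle, 101 ± 33.0 CPM in WT CFA, 81.2 ± 9.49 CPM in iKO vehicle and 56.1 ± 1.998 CPM in iKO CFA. Trpv1, the capsaicin- and heat-gated channel, was at 82.3 ± 22.1, 191 ± 12.1, 135 ± 6.53 and 141 ± 2.28 CPM in the same order. CFA raised Trpa1 in WT by 1.03 ± 0.27 (adjusted p = 0.0333) and Trpv1 by 1.21 ± 0.21 (adjusted p = 0.010004), with both CFA libraries above both vehicle libraries. In iKO the CFA change was -0.53 ± 0.26 for Trpa1 (adjusted p = 0.215) and 0.06 ± 0.21 for Trpv1 (adjusted p = 0.877), neither past the threshold. The interaction, the iKO response minus the WT response, was -1.56 ± 0.37 for Trpa1 (adjusted p = 0.0384) and -1.15 ± 0.30 for Trpv1 (adjusted p = 0.0473). Under vehicle Trpv1 was already higher in iKO than in WT (0.71 ± 0.21, adjusted p = 0.0495), and Trpa1 differed by 0.72 ± 0.26 (adjusted p = 0.0927). Under CFA the iKO minus WT difference was -0.84 ± 0.26 for Trpa1 (adjusted p = 0.183) and -0.44 ± 0.21 for Trpv1 (adjusted p = 0.380).

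Each of these channel calls was lost without WT vehicle library 1. The CFA response in WT was then 0.75 ± 0.30 for Trpa1 (adjusted p = 0.245) and 0.92 ± 0.21 for Trpv1 (0.0923), which passed without each other library (at most 0.0328), and the interactions were -1.26 ± 0.38 for Trpa1 (0.178) and -0.84 ± 0.26 for Trpv1 (0.181). Both Trpa1 calls were also lost without WT vehicle library 2 (1.24 ± 0.31 for CFA in WT, -1.76 ± 0.38 for the interaction). Without any iKO library they were lost as well (0.97 to 1.03 and -1.67 to -1.43), as was the interaction of Trpv1 (-1.20 to -1.06). The higher Trpv1 in iKO under vehicle was kept in 8 settings and lost in 10. The 10 include leaving out WT vehicle library 1 (0.41 ± 0.20) or any iKO library (0.65 to 0.76). Without WT CFA library 1 the CFA response of Trpa1 in WT was 0.64 ± 0.20 and passed (0.0291), and without WT CFA library 2 it was 1.33 ± 0.19 (0.00135), with an interaction of -1.86 ± 0.25 (4.3e-04). With the 4 WT libraries alone neither channel passed for CFA in WT (0.161 and 0.0965). Trpa1 passed as higher in iKO under vehicle without WT CFA library 1 (0.72, adjusted p = 0.00701) or 2 (0.00679) and with the vehicle libraries alone (0.65, 0.0212). It passed as lower with CFA in iKO without WT CFA library 1 (-0.53, adjusted p = 0.0307), 2 (0.0301) or both (0.0313) and with the iKO libraries alone (-0.51, 0.00138). Under CFA it passed as lower in iKO than in WT without WT CFA library 2 (-1.14, adjusted p = 0.00237) and in DESeq2 (-0.84, 0.0392).

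**Figure D2:**
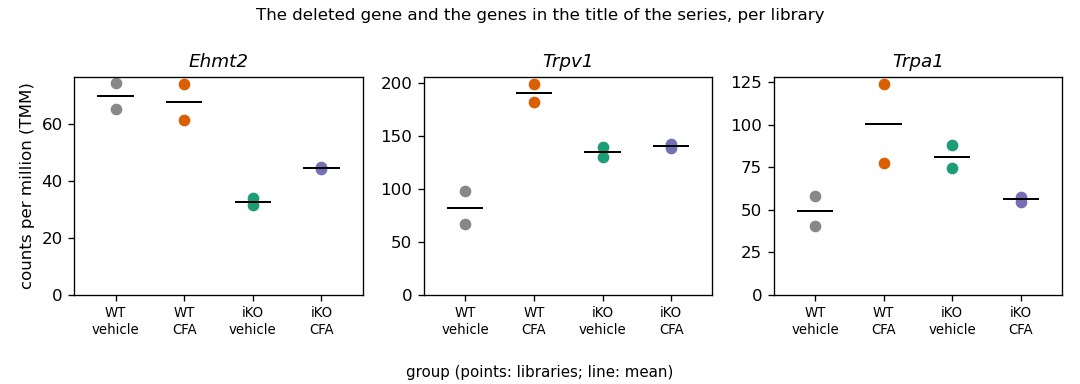
Ehmt2, Trpa1 and Trpv1 in CPM (vertical axis) for the 4 groups (horizontal axis), with a point for each library and a line at the group mean. All 4 iKO libraries lie below all 4 WT libraries for Ehmt2 (at most 45.0 against at least 61.3 CPM), and WT CFA holds the highest mean of Trpa1 (101 CPM) and Trpv1 (191 CPM).

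CFA against vehicle in WT asks which genes a persistently inflamed paw alters in the ganglia of normal mice. Nociceptor genes were among those raised. Calca, which encodes the peptide CGRP, rose by 1.89 ± 0.37 (adjusted p = 0.0133). Bdnf, a neurotrophin, rose by 1.186 ± 0.19 (0.00773), and the itch receptor gene Mrgprx1 by 1.70 ± 0.22 (0.00316). Antibody, B and T cell genes fell almost to 0: Jchain by log2 fold change -10.88 ± 0.73 (adjusted p = 2.4e-04). Mzb1, a plasma cell protein, was at least 1415-fold lower, Cxcl13, a B cell attractant, at least 821-fold lower, Ctla4, a T cell checkpoint receptor, at least 380.2-fold lower. The antibody light chain gene Igl was at least 269-fold lower and Lax1, a lymphocyte adaptor, at least 536-fold lower. Their fitted changes, from -11.72 for Igl to -14.14 for Mzb1, depend on the prior count and are no bound. Rgs1, an immune cell regulator of G proteins, was 678-fold lower (95% counting interval 232 to 3289). In total 3406 of 20235 genes passed, 1643 higher and 1763 lower, and 2215 of them changed by more than 1 on the log2 scale. Of the calls 48.2% were higher, against 6.45% without WT vehicle library 1, 31.3% without library 2, 29.9% to 36.2% without an iKO library and 4.60% with the 4 WT libraries alone. Each gene said here or in the 3 other comparisons of single groups to have risen or fallen had both libraries of one group above both of the other, which chance alone gives for 33.3% of genes.

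The largest rises in WT after CFA included Ndufs5-ps, a pseudogene of a respiratory chain subunit, from 1.17 and 0.477 CPM to 91.4 and 130.3 CPM (7.08 ± 0.42, adjusted p = 1.8e-04), while its parent Ndufs5 fell by 2.17 on the log2 scale (± 0.22, adjusted p = 0.00131). Reads of a gene and its pseudogene can be assigned to either, so both values are uncertain. The steroid reductase gene Srd5a2 rose by 5.61 ± 1.23 (adjusted p = 0.0196), the mitochondrial ATP synthase gene ATP6 by 3.204 ± 0.59 (0.0116), the heparan sulfate sulfotransferase gene Hs3st6 by 3.13 ± 0.57 (0.0111) and Ndufb4c by 2.82 ± 0.60 (0.0181). Magea13, of a gene family best known from testis and tumours, was 15.7-fold higher (95% counting interval 4.01 to 135). Among the largest falls were also the muscle genes Myh1 (at least 650.0-fold lower), Myh2 (at least 236-fold) and Mb (658-fold, 118 to 26034), which were high only in WT vehicle library 1, at 61.8, 22.3 and 20.8 CPM. Of the 20 genes with the largest changes, 9 kept their call without each library in turn, among them Ndufs5-ps, Mzb1, Cxcl13, Lax1, Ctla4, Igl, Jchain and Rgs1. The calls of Srd5a2 and Magea13 were lost without WT vehicle library 1, and those of ATP6, Hs3st6 and Ndufb4c without either WT vehicle library. Those of Myh1, Myh2 and Mb were lost without WT vehicle library 1 or any iKO library, with an adjusted p of at most 0.481 over the settings tried.

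Lists of nociceptor genes lay higher after CFA in WT. Of 14 markers of peptidergic nociceptors 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median change of 0.83 (camera adjusted p = 0.00109). The exception was Gal, the injury-induced peptide galanin, which fell by 1.78 on the log2 scale (± 0.27, adjusted p = 0.00631). Of 19 neuropeptides tested 8 rose and 2 fell (9 and 2 adjusted over the list alone), among them Nppb, a peptide of itch neurons, at 2.32 ± 0.37 (adjusted p = 0.00719) and Nmb at 1.32 ± 0.23 (0.00991), with an adjusted p of 0.00417 for the list. Of 20 non-peptidergic nociceptor markers 3 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.00146), with Mrgpra3 at 1.13 ± 0.22 (0.0139) and Mrgprb5 at -1.54 ± 0.29 (0.0131). Of 19 pan-neuronal genes 7 rose and 0 fell (8 and 1 adjusted over the list alone; 0.00169), with Uchl1 at 1.14 ± 0.21 (adjusted p = 0.0121). Of 28 transduction channels 5 rose and 1 fell (6 and 1 adjusted over the list alone; 0.0154), Piezo1, a pressure-gated channel, falling by 1.57 (± 0.25, adjusted p = 0.00713). Of 58 potassium channels 2 rose and 0 fell (0 and 0 adjusted over the list alone; 0.0179). The adjusted p of these 6 lists with an estimated correlation lay between 0.537 and 0.798.

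Several of these list calls were lost without a single library. Transduction channels did not pass without WT vehicle library 1 (adjusted p = 0.0978) or WT CFA library 1 (0.375), nor did potassium channels without WT vehicle library 1 (0.171) or WT CFA library 1, where the direction turned to lower (0.493). Non-peptidergic nociceptors (adjusted p = 0.194) and pan-neuronal genes (0.253) did not pass without WT CFA library 1. Among the members, Mrgprx1 kept its call without each library, while Gal, Nppb, Bdnf, Nmb, Calca, Mrgpra3, Uchl1 and Piezo1 lost it without WT vehicle library 1 and Mrgprb5 without either WT vehicle library, with adjusted p of at most 0.156 over the settings tried. The other neuronal lists did not pass: sodium channels (0 of 12 higher, 1 lower, adjusted p = 0.372), calcium channels (0 and 1 of 20, 0.736), and C-LTMR markers (0 and 0 of 8, 0.317). Nor did large myelinated neurons (1 and 0 of 18, 0.112), the opioid and cannabinoid system (1 and 1 of 15, 0.423) and glutamate and GABA receptors (2 and 2 of 36, 0.248). Adjusted over the list alone these counts were 0 and 1, 0 and 0, 0 and 0, 0 and 0, 1 and 1, and 0 and 1. Without WT CFA library 2 sodium channels (adjusted p = 0.00542), calcium channels (0.0337), C-LTMR markers (0.0113), large myelinated neurons (0.0171) and glutamate and GABA receptors (0.0140) passed as higher. Large myelinated neurons also passed without WT vehicle library 2 (0.00993).

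Genes of rapid transcriptional response, injury and immune cells were lower after CFA in WT. Of 29 immediate early genes 19 fell and 1 rose (23 and 1 adjusted over the list alone; camera adjusted p = 2.4e-23), with Ccn1 at -5.02 ± 0.26 (adjusted p = 1.3e-04), Fos at -4.62 ± 0.28 (2.0e-04), the mRNA-destabilising Zfp36 at -4.39 ± 0.28 (2.1e-04) and Fosl2 at -2.81 ± 0.19 (2.6e-04). Of 25 nerve injury genes 9 fell and 1 rose (13 and 1 adjusted over the list alone; 6.0e-04), with Atf3, the injury-induced transcription factor, at -1.88 ± 0.24 (adjusted p = 0.00332) and Sox11 at -1.79 ± 0.30 (0.00826). Of 18 lymphocyte genes 15 fell (17 adjusted over the list alone; 2.6e-22), with the T cell co-receptor Cd4 at -4.38 ± 0.46 (adjusted p = 0.00156) and the B cell receptor chain Cd79b at -4.23 ± 0.45 (0.00169). Of 40 cytokines and related mediators 17 fell (27 adjusted over the list alone; 1.5e-14), with Il1b at -4.69 ± 0.48 (adjusted p = 0.00148) and the prostaglandin synthase Ptgs2 at -7.42 ± 0.98 (0.00369). Of 26 macrophage genes 9 fell (10 adjusted over the list alone; 1.4e-06), with the lipopolysaccharide co-receptor Cd14 at -2.52 ± 0.32 (0.00307). Of 43 interferon response genes 15 fell and 1 rose (18 and 1 adjusted over the list alone; 2.4e-06), with Gbp4 at -5.48 ± 0.49 (adjusted p = 9.2e-04). Of 16 skeletal muscle genes 12 fell (14 adjusted over the list alone; 4.1e-04), with a median of -7.60 that includes genes near 0 reads, and Ttn at -5.52 ± 1.16 (0.0174). With an estimated correlation the adjusted p of these 7 lists lay between 0.231 and 0.788. Ccn1, Fos, Zfp36, Fosl2, Cd4, Cd79b, Il1b, Ptgs2, Cd14 and Gbp4 kept their calls without each library, while Atf3, Sox11 and Ttn lost theirs without WT vehicle library 1 (at most 0.250 over the settings tried). Skeletal muscle did not pass without WT CFA library 1 (adjusted p = 0.101).

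Metabolic lists lay higher with CFA in WT. Of 22 enzymes and regulators of cholesterol synthesis 12 rose and 0 fell (15 adjusted over the list alone; camera adjusted p = 2.9e-07), with Dhcr7 at 1.18 ± 0.19 (adjusted p = 0.00713) and Sqle at 1.11 ± 0.20 (0.010004). Of 13 mitochondrial transcripts 7 rose (10 adjusted over the list alone; 3.3e-05), with ND2 at 2.44 ± 0.50 (0.0156), and of 56 respiratory chain genes 14 rose and 1 fell (22 and 1 adjusted over the list alone; 2.1e-06), with Ndufs8 at 1.38 ± 0.29 (0.0164). Against the mean of all libraries, mitochondrial transcripts lay at 0.08 and 1.88 in WT CFA libraries 1 and 2 and at -0.12 and -0.80 in WT vehicle, and the respiratory chain at -0.12 and 0.41 against -0.40 and -0.24. Both lists still passed without WT CFA library 2 (0.0135 each). Of 54 clustered protocadherins, adhesion proteins of neurons, 5 rose (1 adjusted over the list alone; 3.1e-04), with Pcdhgc3 at 0.93 ± 0.18 (0.0131). Granulocyte and mast cell genes (0 of 20 past the threshold, also adjusted over the list alone) and red cell genes (0 of 9, also adjusted over the list alone) passed as higher lists with an adjusted p of 0.0449 each. Of 22 genes of the H3K4 and H3K27 machinery 6 fell and 1 rose (6 and 1 adjusted over the list alone; 0.00937), with the demethylase Kdm6b at -1.82 ± 0.18 (0.00118). These 7 lists had adjusted p with an estimated correlation between 0.554 and 0.798. Kdm6b kept its call without each library, Dhcr7, Sqle and Pcdhgc3 lost theirs without WT vehicle library 1, and ND2 and Ndufs8 without either WT vehicle library (at most 0.188). The granulocyte list turned to lower without WT CFA library 2 (adjusted p = 0.186) and did not pass without WT vehicle library 2 (0.191), and red cell genes turned to lower without WT CFA library 2 (0.562) and did not pass without WT vehicle library 2 (0.245). Protocadherins did not pass without WT CFA library 1 (0.194), nor the H3K4 and H3K27 machinery without WT CFA library 2 (0.0546).

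The remaining lists did not pass for CFA in WT. Of 16 satellite glia genes 4 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0606), the one that fell being Gfap, the glial filament, at -3.17 ± 0.34 (adjusted p = 0.00169). Of 27 genes of the H3K9 methylation machinery 0 rose and 4 fell (0 and 4 adjusted over the list alone; 0.0518), with the demethylase family gene Jmjd1c at -1.78 ± 0.18 (0.00127), and with RLE scaling this list passed as lower (0.0388). Of 35 imprinted genes 4 rose and 6 fell (5 and 7 adjusted over the list alone; 0.455), with Meg3 at -7.36 ± 0.58 (5.2e-04) and Rtl1 at -6.20 ± 0.45 (3.0e-04). Of 17 neighbours of Ehmt2 2 rose and 4 fell (4 and 4 adjusted over the list alone; 0.724), with the complement factor Cfb at -2.80 ± 0.20 (3.0e-04). The members higher and lower were 1 and 4 of 25 for heat shock (adjusted p = 0.648), 0 and 1 of 18 for myelinating Schwann cells (0.888), 0 and 1 of 12 for non-myelinating Schwann cells (0.372). They were 0 and 4 of 24 for fibroblasts and matrix (0.153), 1 and 3 of 16 for endothelium (0.0909), 1 and 0 of 12 for pericytes (0.888), and 1 and 1 of 9 for adipocytes (0.534) and 1 and 2 of 10 for spinal cord (0.832). They were 1 and 0 of 8 for bone and cartilage (0.449), 0 and 0 of 10 germline genes (0.509), 2 and 0 of 11 neighbours of Avil (0.0518), 0 and 1 of 4 sex-linked genes (0.534) and 3 and 0 of 75 ribosomal proteins (0.159). Adjusted over the list alone heat shock had 2 and 4, adipocytes 3 and 1, neighbours of Avil 3 and 0 and ribosomal proteins 2 and 0, and the other 9 lists had the same counts. Gfap, Jmjd1c, Meg3, Rtl1 and Cfb kept their calls without each library. Without WT CFA library 2 fibroblasts (adjusted p = 7.5e-06), endothelium (2.3e-05) and myelinating Schwann cells (0.00363) passed as lower, ribosomal proteins as lower (2.1e-04) and neighbours of Avil as higher (0.0490). Leaving out WT CFA library 1, ribosomal proteins passed as higher (1.5e-10), satellite glia as higher (7.6e-04) and the H3K9 machinery as lower (2.5e-04). Without WT vehicle library 1 ribosomal proteins (0.00528) and satellite glia (0.0133) passed as higher, and without WT vehicle library 2 fibroblasts (0.00974) and the H3K9 machinery (0.0266) as lower.

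Across all comparisons no list call held with an estimated correlation. The count of genes for CFA in WT was 248 without WT vehicle library 1, 1242 without WT vehicle library 2, 7546 without WT CFA library 1 and 6611 without WT CFA library 2, and between 1695 and 1796 without an iKO library. The median, mean and test of a list differed in sign for calcium channels, neighbours of Ehmt2, glutamate and GABA receptors and the opioid and cannabinoid system, none of which passed.

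CFA against vehicle in iKO asks the same in mice with the deletion of G9a. The 8 genes past the threshold all rose. Cfd, the fat cell protease adipsin, rose from 0.392 and 0.115 to 28.8 and 44.0 CPM (7.11 ± 0.80). Cd177, a neutrophil surface protein, rose by 3.88 ± 0.46, Clec3b by 3.64 ± 0.39, and the fibroblast gene Pi16 by 2.61 ± 0.29. Erdr1 rose by 2.51 ± 0.29, elastin (Eln) by 2.50 ± 0.27 and Vwf, the von Willebrand factor of endothelium, from 21.5 and 21.2 to 67.0 and 72.9 CPM (1.71 ± 0.17). Their adjusted p was 0.0382, and 0.0464 for Cd177. In this edgeR fit 0 genes passed as lower, where Trim66 at -2.22 ± 0.31 (adjusted p = 0.0581) and the nuclear receptor gene Esrrg at -1.81 ± 0.30 (0.0831) came nearest. Other edgeR fits had lower calls: 17 of 181 with legacy = FALSE, 167 of 510 with no filter on low counts and 4294 of 8322 with the 4 iKO libraries alone. At an unadjusted p under 0.05 there were 5791 genes against 1012 expected by chance. DESeq2 called 3449 genes and limma-voom 26. The count was 0 without either WT vehicle library or any iKO library, so that Cfd, Cd177, Clec3b, Pi16, Erdr1, Eln and Vwf lost their calls (adjusted p at most 0.388), and it was 6981 without WT CFA library 1, 3772 of them lower, and 6973 without WT CFA library 2, 3802 of them lower.

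Whole lists moved apart with CFA in iKO, though few members passed over all genes. Of 9 adipocyte genes 1 rose (9 adjusted over the list alone), with a median change of 4.94 (camera adjusted p = 1.0e-11), and of 20 granulocyte and mast cell genes 0 passed (19 rose adjusted over the list alone; median 3.82, 1.3e-20). Red cell genes (0 of 9; 7 rose adjusted over the list alone; median 2.13, adjusted p = 1.7e-04), macrophage genes (0 of 26; 23 rose; 1.48, 5.8e-15), fibroblast and matrix genes (1 of 24; 23 rose; 1.28, 2.5e-17) and mitochondrial transcripts (0 of 13; 12 rose; 1.86, 1.1e-10) lay higher too. So did myelinating Schwann cell genes (0 of 18; 12 rose adjusted over the list alone; 1.09, 8.9e-08), endothelium (1 of 16; 13 rose; 0.94, 4.0e-11), ribosomal proteins (0 of 75; 65 rose; 0.83, 8.7e-19) and the interferon response (0 of 43; 0 adjusted over the list alone; 1.15, 9.7e-10). Cytokines (0 of 40; 11 rose adjusted over the list alone; 1.09, 1.9e-07), lymphocyte genes (0 of 18; 4 rose; 1.49, 2.4e-04), pericytes (0 of 12; 8 rose; 0.92, 2.4e-04) and the respiratory chain (0 of 56; 0 adjusted over the list alone; 0.37, 2.0e-04) completed the higher lists. Among the 13 lower lists were potassium channels (0 of 58; 14 fell adjusted over the list alone; median -0.80, 1.4e-10), sodium channels (0 of 12; 7 fell; -1.04, 2.0e-05), and calcium channels (0 of 20; 11 fell and 1 rose; -0.96, 4.6e-06). Large myelinated neurons (0 of 18; 12 fell; -0.92, 1.2e-07) and pan-neuronal genes (0 of 19; 0 adjusted over the list alone; -0.51, 2.4e-04) lay lower too, as did glutamate and GABA receptors (0 of 36; 6 fell; -0.68, 1.0e-04), protocadherins (0 of 54; 1 fell; -0.57, 1.5e-04) and transduction channels (0 of 28; 3 fell; -0.36, 0.00223). Lower lists other than those of neurons were non-myelinating Schwann cells (0 of 12; 6 fell adjusted over the list alone; -0.72, 1.7e-04), sterol synthesis (0 of 22; 0 adjusted over the list alone; -0.42, 0.00165), the H3K4 and H3K27 machinery (0 of 22; 3 fell; -0.40, 0.00165) and the H3K9 machinery (0 of 27; 0 adjusted over the list alone; -0.40, 0.0139). With an estimated correlation the adjusted p of the 27 lists that passed lay between 0.460 and 0.602. Of these, 26 kept call and direction without each library, and C-LTMR markers (-0.69, 0.0308) did not pass without iKO vehicle library 1 (0.156) or iKO CFA library 2 (0.0821). Non-peptidergic nociceptors passed as lower without iKO vehicle library 2 (0.0195). The median, mean and test differed in sign for neighbours of Ehmt2, imprinted genes, the opioid and cannabinoid system, skeletal muscle and spinal cord.

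Many genes at a small unadjusted p differed the same way between the WT CFA libraries, which had the same treatment. Of the 5791 genes at an unadjusted p under 0.05 for CFA in iKO, 5360 (92.6%) differed in the same direction between WT CFA library 2 and WT CFA library 1, against 75.3% of all genes. The slope of these differences on the change in iKO was 0.569 over all genes. Of the genes past the threshold, Cfd (1.39 and 5.92 CPM in libraries 1 and 2) and Cd177 (0.988 and 2.60 CPM) differed there, while Vwf (17.5 and 18.2 CPM), Eln (3.31 and 3.97 CPM) and Clec3b (1.34 and 1.71 CPM) hardly did. A fit with 1 spread for all groups favours genes on which the WT CFA libraries agree. With iKO vehicle at 0 and iKO CFA at 1, the median position was 0.0886 for WT CFA library 1 and 0.966 for WT CFA library 2. The adipocyte list lay 1.55 higher in WT CFA library 2 than in library 1, the granulocyte list 2.15, the red cell list 3.01 and the myelinating Schwann cell list 1.04.

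**Figure D3:**
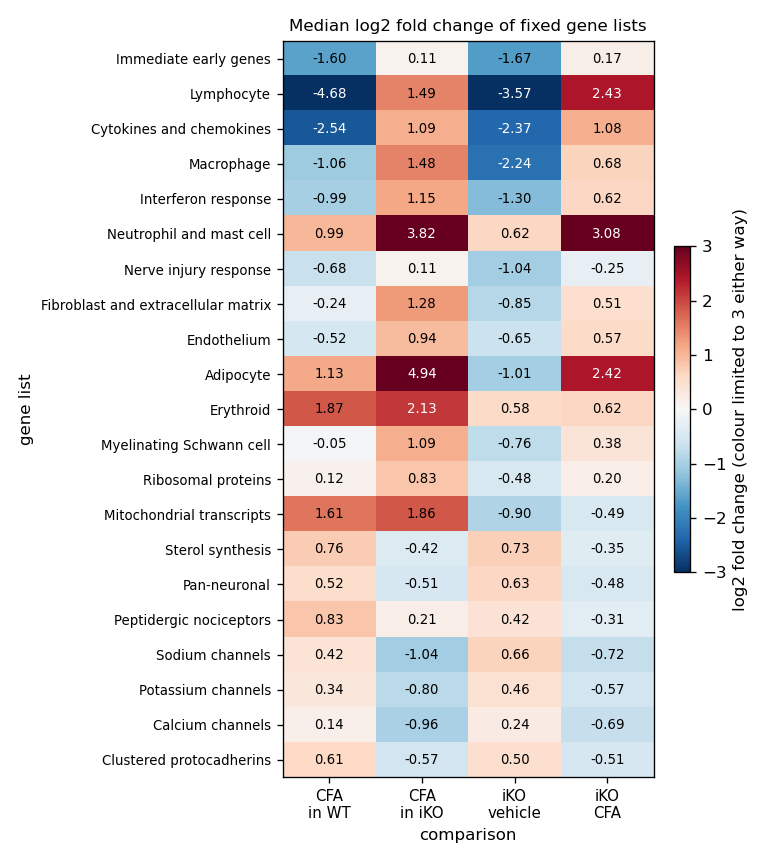
Median log2 fold change (colour, limited to 3 either way) of fixed gene lists (vertical axis) in comparisons (horizontal axis). Adipocyte genes have a median of 4.94 with CFA in iKO, and immediate early genes one of -1.60 with CFA in WT and -1.67 in iKO under vehicle.

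The interaction tests whether the CFA response differed between iKO and WT, the question the series title raises for Trpa1 and Trpv1. Genes of plasma cells and lymphocytes had the largest values and were far lower in the other groups than in WT vehicle. The fitted difference was 13.84 ± 0.89 for Jchain (adjusted p = 8.4e-04), 16.26 ± 1.197 for Mzb1 (0.00153), 14.64 ± 2.25 for Cxcl13 (0.0114), 14.51 ± 1.13 for Igl (0.00168), 14.04 ± 2.25 for Lax1 (0.0131) and 12.61 ± 2.53 for Ctla4 (0.0268). The ubiquitin-like gene Ubd (11.88 ± 1.40, 0.00491), the guanylate-binding gene Gbp10 (10.67 ± 1.64, 0.00896) and Rasal3 (9.84 ± 1.13, 0.00326) followed, and all of these fitted values involve groups at or near 0 reads and are no bound. Lower in the iKO response were Ndufs5-ps (-6.02 ± 0.70, adjusted p = 0.00331), the phosphate transporter gene Slc34a2 (-3.22 ± 0.62), the sulfotransferase gene Gal3st3 (-3.03 ± 0.70) and Sapcd1 (-2.997 ± 0.70). So were Magea13 (-2.94 ± 0.66, with 2 reads over WT vehicle and no bound either), the potassium channel subunit gene Kcne1l (-2.94 ± 0.56), the matrix linker gene Hapln4 (-2.93 ± 0.58) and Pcdha12 (-2.77 ± 0.48). In total 1895 genes passed, 1253 higher and 642 lower, and 1841 by more than 1 on the log2 scale. Mzb1, Igl, Jchain, Ubd, Rasal3 and Ndufs5-ps kept their calls without each library. Without WT vehicle library 1 those of Cxcl13, Lax1, Ctla4, Gbp10 (adjusted p = 0.0671), Slc34a2, Gal3st3, Sapcd1, Magea13, Kcne1l, Hapln4 and Pcdha12 were lost. For Cxcl13, Lax1 and Ctla4 the adjusted p then or without an iKO library reached 1, and the last 7 were also lost without any iKO library, and Slc34a2, Gal3st3, Sapcd1 and Magea13 without WT vehicle library 2 (at most 0.191). The count was 212 without WT vehicle library 1, 975 without library 2, 4653 and 8366 without WT CFA libraries 1 and 2, and between 299 and 478 without an iKO library. Of the calls 66.1% were higher, against 98.6% without WT vehicle library 1, 76.0% without library 2, 51.2% and 44.8% without WT CFA libraries 1 and 2 and 96.0% to 98.3% without an iKO library.

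Immediate early genes, not called in iKO, and immune lists had a more positive CFA response in iKO than in WT. Of 29 immediate early genes 17 were higher and 0 lower (22 adjusted over the list alone; camera adjusted p = 1.8e-19), with Fos at 4.81 ± 0.37 (adjusted p = 0.00108). Of 18 lymphocyte genes 13 were higher (18 adjusted over the list alone; 5.8e-25), with Cd79b at 5.69 ± 0.60 (0.00241), and of 26 macrophage genes 20 (24 adjusted over the list alone; 1.9e-18), with Cd14 at 3.31 ± 0.44 (0.00538). Of 40 cytokines 16 were higher (31 adjusted over the list alone; 5.3e-19), with Il1b at 6.88 ± 0.67 (0.00204), and of 43 interferon response genes 17 (22 adjusted over the list alone; 2.5e-14), with Gbp4 at 6.91 ± 0.64 (0.00172). Neuronal and sterol lists had a more negative one. Of 19 pan-neuronal genes 6 were lower (13 adjusted over the list alone; 2.5e-06), with the synaptic vesicle gene Syp at -1.33 ± 0.28 (0.0255). Of 22 sterol genes 11 were lower (19 adjusted over the list alone; 2.3e-09), with Dhcr7 at -1.70 ± 0.26 (0.00926), and of 58 potassium channels 6 (15 adjusted over the list alone; 5.0e-09), with Kcns1 at -1.66 ± 0.37 (0.0318). Of 12 sodium channels 3 were lower (10 lower and 1 higher adjusted over the list alone; 6.5e-04), with Scn9a, a sodium channel of nociceptors, at -1.45 ± 0.37 (0.0444). With an estimated correlation the adjusted p of the 25 lists that passed lay between 0.238 and 0.653. Fos, Cd79b, Cd14, Il1b and Gbp4 kept their calls without each library, while Syp, Dhcr7, Kcns1 and Scn9a lost theirs without WT vehicle library 1 or any iKO library, and Scn9a also without WT vehicle library 2 (at most 0.194). Of the 25 lists, 22 kept call and direction without each library. Without WT CFA library 1 calcium channels, pericytes and C-LTMR markers did not pass. Nor did C-LTMR markers without WT vehicle library 1, iKO vehicle library 1 or iKO CFA library 2. Neuropeptides passed as lower only without WT CFA library 1 or iKO vehicle library 2. Peptidergic nociceptors did without WT CFA library 1 or WT vehicle library 2, and heat shock as higher without the latter. Leaving out WT CFA library 2 added non-myelinating Schwann cells (lower), red cell genes (higher) and mitochondrial transcripts (higher). Without WT CFA library 1 the respiratory chain passed as lower. The median, mean and test differed in sign for neighbours of Ehmt2, the H3K9 machinery, the opioid and cannabinoid system and satellite glia.

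IKO against WT under vehicle asks what the deletion of G9a alters without inflammation. Tph2, the neuronal enzyme of serotonin synthesis, rose from 1.24 and 1.31 to 88.6 and 82.0 CPM (6.06 ± 0.21, adjusted p = 1.2e-05), and Serpinb5, an epithelial serpin, from 1.57 and 1.43 to 212 and 184 CPM (7.04 ± 0.32, 6.4e-05). Genes almost without reads in WT rose as well: the cystatin gene Cst12 was 712-fold higher (95% counting interval 127 to 28148), Nt5el 333-fold (59.4 to 13180), Crct1 311-fold (55.5 to 12318) and Magea13 239-fold (65.8 to 1978). Among the largest falls were genes highest in WT vehicle: Jchain (-8.59 ± 0.66, adjusted p = 3.3e-04), Cxcl13 (1398-fold, 387 to 11550), Ubd (at least 284-fold) and Lax1 (-8.46 ± 1.01, 0.00296). They also included Ctla4 (-8.22 ± 0.96, 0.00276), Mzb1 (-8.01 ± 0.60, 6.2e-04), Igl (-7.47 ± 0.61, 8.2e-04), the noncoding RNA Rmrp (-7.73 ± 1.35, 0.00851) and Myh2 (402-fold, 111 to 3326). The pseudogene H2af-ps2 was 259-fold lower (46.0 to 10270). In total 3564 genes passed, 1676 higher and 1888 lower, 2456 of them by more than 1 on the log2 scale. Of the 20 genes with the largest changes 17 kept their call without each library. Crct1 lost it without WT vehicle library 1 (adjusted p = 0.0510), Rmrp without that library or either iKO vehicle library (at most 0.170) and Myh2 without that library or any iKO library (at most 0.496). The count was 366 without WT vehicle library 1, 1799 without library 2, 8604 and 8606 without WT CFA libraries 1 and 2, 579 and 390 without iKO vehicle libraries 1 and 2, and 1985 and 2052 without iKO CFA libraries 1 and 2. Of the calls 47.0% were higher, against 23.5% and 35.2% without WT vehicle libraries 1 and 2, 53.9% and 54.1% without WT CFA libraries 1 and 2 and 31.1% to 36.4% without an iKO library.

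Many list members moved in iKO under vehicle as they had with CFA in WT, and both comparisons use the WT vehicle libraries. Of the genes raised by CFA in WT, 829 were also higher in iKO under vehicle (136 expected from independent calls). Of those lowered 1245 were also lower (164 expected). In 20 simulations without any effect the means were 0.05 and 0. These simulations called a mean of only 0.15 genes in each comparison, so they set no baseline for the counts. Across genes, which are not independent replicates, the changes had a correlation of 0.664, against 0.507 in these simulations, and a covariance of 1.86 against 0.280. With WT vehicle library 1 for CFA in WT and library 2 for iKO under vehicle, 28 genes were higher and 281 lower in both (covariance 1.72), and with these libraries exchanged 12 and 228 (1.65). Part of the excess may come from the shared libraries. Of 29 immediate early genes 21 fell (23 fell and 1 rose adjusted over the list alone; camera adjusted p = 6.1e-22), with Fos at -4.30 ± 0.28 (adjusted p = 2.3e-04). Of 25 nerve injury genes 15 fell (16 adjusted over the list alone; 1.0e-07), with Gal at -3.09 ± 0.29 (8.2e-04), Atf3 at -2.63 ± 0.25 (8.5e-04) and Sprr1a at -5.27 ± 0.68 (0.00276). Of 26 macrophage genes 22 fell (24 adjusted over the list alone; 4.1e-14), with Cd14 at -3.18 ± 0.33 (0.00111), and of 18 lymphocyte genes 12 (14 adjusted over the list alone; 2.8e-13). Of 22 sterol genes 14 rose (18 adjusted over the list alone; 5.8e-07), with Dhcr7 at 1.35 ± 0.19 (0.00389), and of 19 pan-neuronal genes 5 rose (7 adjusted over the list alone; 9.4e-04), with Thy1 at 1.17 ± 0.20 (0.00797). Of 28 transduction channels 9 rose and 1 fell (9 and 1 adjusted over the list alone; 0.00243), with the acid-sensing channel Asic1 at 1.70 ± 0.27 (0.00627). With an estimated correlation the adjusted p of the 20 lists that passed lay between 0.240 and 0.750. Fos, Gal, Atf3, Sprr1a and Cd14 kept their calls without each library, whereas Dhcr7 lost its call without WT vehicle library 1, Thy1 without that library or either iKO vehicle library, and Asic1 without that library or iKO vehicle library 2 (at most 0.0836). Without WT vehicle library 1 sodium channels (adjusted p = 0.0758), non-peptidergic nociceptors (0.150), myelinating Schwann cells (0.256), skeletal muscle (0.538) and the respiratory chain (0.116) did not pass, and non-peptidergic nociceptors did not without iKO vehicle library 1 (0.129). Leaving out WT vehicle library 2 added glutamate and GABA receptors (higher; 0.0476), heat shock (lower; 0.00355), adipocytes (lower; 0.0359), the H3K4 and H3K27 machinery (lower; 0.0476) and mitochondrial transcripts (lower; 0.0305). The H3K4 and H3K27 machinery also passed without WT CFA library 1 (0.0287) or 2 (0.0279), mitochondrial transcripts without either of these (0.0112 and 0.0127) or iKO vehicle library 2 (0.0205), and granulocyte genes as higher without WT vehicle library 1 (0.0235) or iKO vehicle library 2 (0.00777). The median, mean and test differed in sign for bone and cartilage, neighbours of Ehmt2, neuropeptides and satellite glia.

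Under CFA, iKO against WT asks what the deletion of G9a alters in inflamed mice. Genes near 0 in WT were again higher: Cst12 at least 294-fold, the protease gene Prss41 at least 186-fold, Nt5el 221-fold (95% counting interval 39.3 to 8768) and Acoxl 125-fold (34.2 to 1037), and Gad1, the enzyme of GABA synthesis, rose by 5.34 ± 0.36 (adjusted p = 3.1e-04). Vessel and matrix genes rose: Vwf by 1.97 ± 0.18 (adjusted p = 0.00134) and Pi16 by 2.84 ± 0.29 (0.00312). The antibody genes Jchain (5.25 ± 0.61, 0.00478), Mzb1 (at least 24.6-fold) and Igl (at least 10.5-fold) were higher, at levels of at most 31.5, 1.18 and 0.493 CPM. Lower were H2af-ps2 (at least 110-fold), Ndufs5-ps (-7.55 ± 0.43, adjusted p = 1.3e-04), the histone gene H2ac18 (-3.97 ± 0.60, 0.0160) and Wdfy1 (-2.81 ± 0.25, 0.00136). So were Tmem267 (-2.68 ± 0.37, 0.0112), the netrin receptor gene Unc5d (-2.55 ± 0.41, 0.0228), Cpne9 (-2.38 ± 0.46, 0.0435) and the potassium channel subunit gene Kcnv1 (-2.34 ± 0.28, 0.00587). The parent gene Ndufs5 rose by 3.24 ± 0.23 (3.1e-04). The pseudogenes Glo1-ps (6.55 ± 0.33, 6.8e-05) and Rpl15-ps6 (6.60 ± 0.59, 0.00134) rose. In total 345 genes passed, 303 higher and 42 lower, 342 of them by more than 1 on the log2 scale. Of the 20 genes with the largest changes 13 kept their call without each library, as did Gad1, Vwf, Pi16, Jchain and Ndufs5. Mzb1, Igl, H2ac18, Unc5d, Cpne9 and Kcnv1 lost theirs without either iKO CFA library and Tmem267 without iKO CFA library 1 (0.0836), with at most 0.484 over the settings tried. Mzb1 also lost it without WT CFA library 1 or any iKO library, Igl and H2ac18 without either WT vehicle library, Unc5d without either WT vehicle or any iKO library, and Cpne9 without any library but WT CFA library 2. The count was 172 and 167 without WT vehicle libraries 1 and 2, 669 and 5860 without WT CFA libraries 1 and 2, 152 without either iKO vehicle library, and 78 and 65 without iKO CFA libraries 1 and 2. Of the calls 87.8% were higher, against 74.6% without WT CFA library 1, 43.0% without WT CFA library 2 and 89.2% to 93.6% without any other library.

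Of 29 lists past the threshold in iKO under CFA 14 were higher, immune, vessel and fat genes among them, and 15 lower. The lower ones were lists of neurons and nerve injury, non-myelinating Schwann cells (0 of 12; 3 fell adjusted over the list alone; camera adjusted p = 0.00631), sterol synthesis (0 of 22; 0 adjusted over the list alone; 5.9e-04) and the H3K4 and H3K27 machinery (0 of 22; 0 adjusted over the list alone; 0.0193). Of 20 granulocyte genes 6 rose (18 adjusted over the list alone; camera adjusted p = 2.8e-21), with Mpo at 3.06 ± 0.46 (adjusted p = 0.0157), and of 18 lymphocyte genes 6 rose (9 adjusted over the list alone; 7.5e-15), with the T cell receptor partner Cd3e at 4.77 ± 0.60 (0.00733). Of 24 fibroblast and matrix genes 7 rose (9 adjusted over the list alone; 4.2e-10), with Col6a2 at 1.62 ± 0.26 (0.0226), and of 16 endothelial genes 2 rose (7 adjusted over the list alone; 5.4e-07), with Plvap at 2.75 ± 0.36 (0.00997). Of 40 cytokines 2 rose (7 adjusted over the list alone; 7.0e-09), with a median of 1.08 and of 0.99 with genes at the floor set to their bounds, and with Il1rn, the interleukin 1 receptor antagonist, at 3.88 ± 0.50 (0.00788). Of 9 adipocyte genes 2 rose (6 adjusted over the list alone; 5.0e-07), with Fabp4 at 3.10 ± 0.53 (0.0275), and of 10 spinal cord markers 2 rose (3 adjusted over the list alone; 0.00139), Gad1 among them. Of 58 potassium channels 1 fell (2 adjusted over the list alone; median -0.57, 1.7e-08), and of 54 protocadherins 0 passed (0 adjusted over the list alone; -0.51, 2.6e-06). Of 18 genes of large myelinated neurons 1 fell (3 adjusted over the list alone; 6.8e-04), the calcium-binding protein gene Calb1 at -1.98 ± 0.24 (0.00542). With an estimated correlation the adjusted p of the 29 lists that passed lay between 0.412 and 0.746. Without either iKO CFA library Mpo, Col6a2, Plvap, Il1rn, Fabp4 and Calb1 lost their calls, as did Cd3e without iKO CFA library 2, Col6a2 without either WT vehicle library and Fabp4 without WT vehicle library 2 (at most 0.190).

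Of those 29 lists 11 kept call and direction without each library. Without WT CFA library 1 potassium channels (adjusted p = 0.0520), pan-neuronal genes (0.0680), the interferon response (0.142), non-myelinating Schwann cells (0.207), non-peptidergic nociceptors (0.288), pericytes (0.288), and skeletal muscle (0.319) did not pass. Nor did C-LTMR markers (0.341), macrophages (0.361), transduction channels (0.418), calcium channels (0.418), the H3K4 and H3K27 machinery (0.587) and sodium channels (0.995). Myelinating Schwann cells (0.346), red cell genes (0.586) and ribosomal proteins (3.3e-04) then turned to lower. Without WT CFA library 2 neuropeptides (0.0811), nerve injury genes (0.322) and skeletal muscle (0.100) did not pass. Without iKO CFA library 1 transduction channels (0.0510), nerve injury genes (0.111), myelinating Schwann cells (0.118), red cell genes (0.127) and ribosomal proteins (0.103) did not, nor did sodium channels (0.0730) and myelinating Schwann cells (0.0750) without iKO CFA library 2. Peptidergic nociceptors passed as lower without WT vehicle library 1 (0.0453) or 2 (0.0449) or WT CFA library 1 (0.0203), satellite glia as lower without WT CFA library 1 (0.00460), the H3K9 machinery as lower without WT CFA library 2 (6.6e-04) and immediate early genes as higher without iKO CFA library 1 (0.0463). Mitochondrial transcripts and the respiratory chain passed as lower without WT CFA library 1 (1.3e-14 and 0.00107) and as higher without WT CFA library 2 (0.00754 and 1.5e-06). With RLE scaling red cell genes (0.0503) and myelinating Schwann cells (0.0552) did not pass. The median, mean and test differed in sign for heat shock and the opioid and cannabinoid system.

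Genes that differed between the genotypes in the same direction under both treatments were mostly higher in iKO. Tph2 was at 1.28 CPM in WT and 85.3 CPM in iKO under vehicle, and at 1.60 and 80.7 CPM under CFA. Serpinb5 was at 1.502 and 198 CPM under vehicle and 1.85 and 161 CPM under CFA. Higher under both treatments were 137 genes (25.1 expected from independent calls). Lower were 11, such as Kcnv1, Calb1 and Wdfy1 (3.92 expected). Another 53 were lower under vehicle and higher under CFA (28.3 expected). Of the 137, 66 were under 1 CPM in every WT library and 8 had pseudogene symbols. These comparisons share 1 estimate of spread but no library, so calls are not independent. Fewer were raised in both without a WT vehicle or iKO library, more without a WT CFA library. Of the 34 germline genes 10 were tested and 0 passed in edgeR in any comparison of single groups (0 adjusted over the list alone), where Sycp1 had the smallest adjusted p, 0.0551 at -8.22 ± 2.33 in iKO under vehicle.

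**Figure D4:**
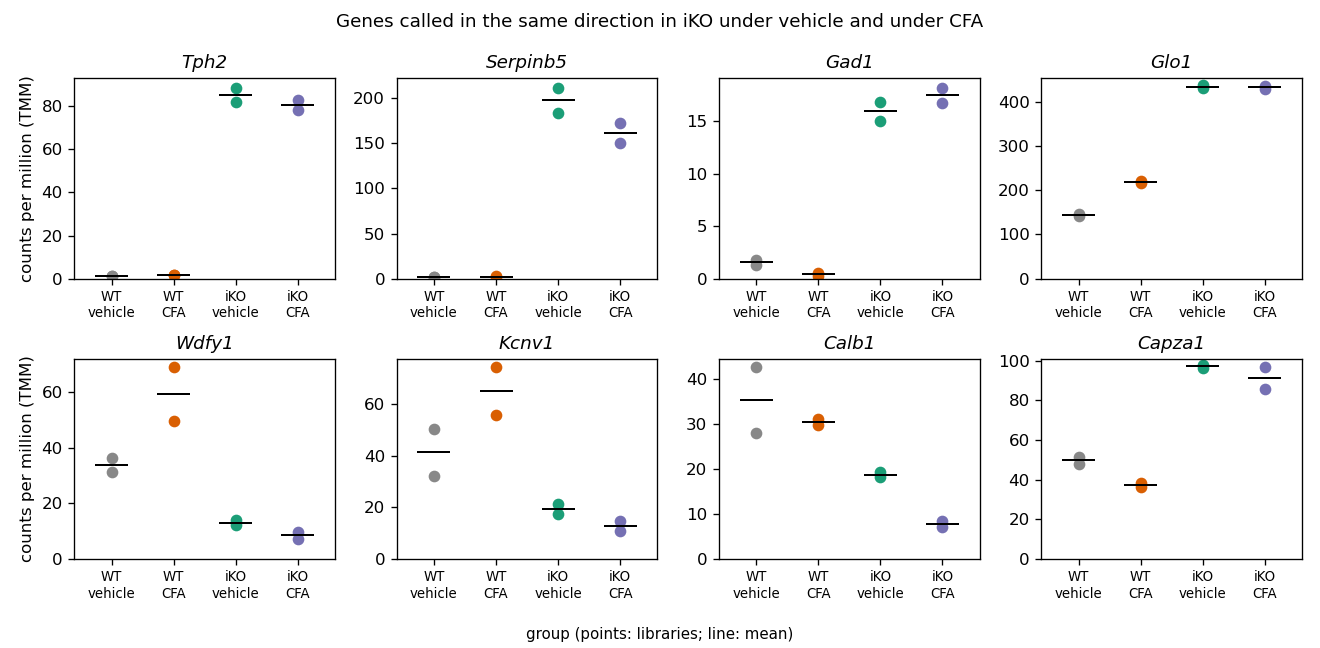
Genes that differed in the same direction between iKO and WT under vehicle and under CFA, in CPM (vertical axes) for the 4 groups (horizontal axes), with a point for each library and a line at the group mean. Tph2 lies between 78.2 and 88.6 CPM in the 4 iKO libraries and between 1.24 and 1.68 CPM in the 4 WT libraries.

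Genes moved by CFA in WT lay the other way in iKO under CFA more often than independent calls give, in a comparison that shares the WT CFA libraries. Ndufs5-ps and other genes made 15 that rose with CFA in WT and were lower in iKO under CFA (3.41 expected). Jchain, Mzb1, Igl and Vwf were among 108 that fell and were higher (26.4 expected). Across genes, which are not independent replicates, the changes had a correlation of -0.486, against -0.497 in 20 simulations without any effect, and a covariance of -1.26 against -0.274. The simulations gave 0 opposite calls, but without any effect they call hardly any genes, so they set no baseline for the counts. With WT CFA library 1 for CFA in WT and library 2 for iKO under CFA, 79 genes rose and were lower and 182 fell and were higher (correlation -0.262, covariance -1.02), and with these libraries exchanged 181 and 488 (-0.151 and -0.626). Part of the excess may come from the shared libraries. In the comparison without shared libraries, CFA in WT against CFA in iKO, the correlation was -0.0286.

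Averaged over treatments, 1129 genes differed between the genotypes, 643 higher and 486 lower in iKO. Tph2 (5.86 ± 0.14, adjusted p = 7.0e-07), Serpinb5 (6.75 ± 0.22, 4.2e-06) and Afp (5.36 ± 0.22, 1.4e-05) were among the genes with the smallest p, with all 4 iKO above all 4 WT libraries. Ehmt2 passed as above, while Trpa1 (-0.06, adjusted p = 0.885) and Trpv1 (0.14, 0.645) did not. Of 10 lists past the threshold 3 were higher and 7 lower, with granulocyte genes (8 of 20 rose; 16 adjusted over the list alone; 1.8e-11) and immediate early genes (10 of 29 fell; 20 adjusted over the list alone; 2.2e-13) first, and adjusted p of 0.486 to 0.973 with an estimated correlation. Mitochondrial transcripts (0 of 13; 0 adjusted over the list alone; lower, 0.0421) and the respiratory chain (1 of 56 rose; 1 adjusted over the list alone; 0.0378) did not pass with RLE scaling (0.0579 each). The immediate early genes were lower in iKO under vehicle, but under CFA they lay higher without passing (camera adjusted p = 0.0847). Averaged over genotypes, 2364 genes differed with CFA, 1327 higher and 1037 lower. Malat1 (-2.78 ± 0.21, adjusted p = 0.00116), Meg3 (-4.40 ± 0.36, 0.00151) and Fos (-2.22 ± 0.18, 0.00157) fell, and Trpv1 rose (0.64 ± 0.15, 0.0335), while Ehmt2 (0.20 ± 0.12, 0.297) and Trpa1 (0.25, 0.391) did not pass. Of 23 lists 14 were higher and 9 lower, with granulocyte genes (13 of 20 rose; 16 adjusted over the list alone; 3.3e-14) first, and adjusted p of 0.582 to 0.730 with an estimated correlation. Of the calls for genotype 57.0% were higher, against 49.97% to 69.6% without a library. For CFA 56.1% were, against 10.2% to 15.8% without any WT vehicle or iKO library and 43.8% and 48.9% without WT CFA libraries 1 and 2. The CFA call of Trpv1 was lost without either WT vehicle library (0.123 and 0.0657) or any iKO library (0.124 to 0.152).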

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

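Tests of gene length and GC content, a spread shared by all groups and other sample splits were set before results were seen. Those of library sets, a vehicle library under a CFA label, neuron share, WT vehicle libraries, linked alleles and strain background were chosen later. Intervals treat genes, not libraries, as replicates.

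A test of the difference between both CFA responses picked out 1895 genes. Trpa1 (-1.56) and Trpv1 (-1.15) had a lower CFA response in iKO than in WT. The largest differences were those of Mzb1 (16.26), Cxcl13 (14.64), Igl (14.51), Lax1 (14.04), Jchain (13.84), Ctla4 (12.61), Ubd (11.88), Gbp10 (10.67) and Rasal3 (9.84), fitted values of genes near 0 reads in some groups that are no bound. On the other side were Ndufs5-ps (-6.02), Slc34a2 (-3.22), Gal3st3 (-3.03), Sapcd1 (-2.997), Magea13 (-2.94, no bound either), Kcne1l (-2.94), Hapln4 (-2.93) and Pcdha12 (-2.77). Without WT vehicle library 1 the count was 212, and Trpa1 (-1.26 ± 0.38, adjusted p = 0.178) and Trpv1 (-0.84 ± 0.26, 0.181) no longer passed.

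CFA called 3406 genes in WT and 8 in iKO. Fitted on the 4 iKO libraries alone, 8322 genes passed for CFA in iKO, which is consistent with the spread between the WT CFA libraries limiting that count in the fit to all groups. At the genes called for CFA in WT, the iKO vehicle group lay 0.833 of the way from WT vehicle to WT CFA (95% interval 0.818 to 0.847), though it had received no CFA, and over all genes both WT vehicle libraries lay outside the range of the other 6 for 37.7%, against 7.14% by chance. These genes were chosen for a difference from WT vehicle, which favours such a position, but much of what was called for CFA in WT may reflect how the WT vehicle libraries differed from every other group, the handling or dissection of those samples included. A response to CFA in WT stays open as a part of it, since no second WT vehicle group exists to test it, and this holds for Trpa1 and Trpv1 as well. The interaction (1895 genes) and iKO under vehicle (3564 genes) use the same WT vehicle libraries. Their calls, those of Trpa1 and Trpv1 included, have the same limit.

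Fat, blood, matrix and myelin genes were higher and channel genes lower with CFA in iKO, and of the genes at an unadjusted p under 0.05, 92.6% (95% interval 91.9 to 93.2) differed in the same direction between the WT CFA libraries, against 75.3% of all genes. This is consistent with library sets as a part of the cause, in which WT CFA library 1 goes with iKO vehicle and WT CFA library 2 with iKO CFA. A vehicle library under a CFA label as WT CFA library 1 would give the same value, but at 81.7% (80.8 to 82.5) of the genes where WT vehicle stood apart that library lay nearer to the 5 others, which argues against an exchange with the WT vehicle group and leaves a sample from outside it open. The tables argue against gene length and GC content, since 87.0% (77.4 to 98.2) of the difference was kept after removing that trend. Medians of other cell types spanned 5.66, which argues against fewer neurons as the only cause, but not as a part. A CFA effect in iKO stays open, as each iKO treatment lies in 1 set. The change in iKO exceeded that between WT CFA libraries for adipocytes (4.94 against 1.55) and granulocytes (3.82, 2.15), but not red cells (2.13, 3.01). WT CFA library 1 lay nearer to iKO vehicle (root mean square log2 distance 0.937 and 0.929) than to library 2 (1.12). Library 2 lay nearer to library 1 than to iKO CFA (1.15 and 1.188).

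For the 137 genes higher in iKO than in WT under both treatments the choice was repeated without WT CFA library 1 and iKO vehicle library 1, and of the 148 genes it gave 100% (97.5 to 100) were lower in the first of these libraries than in the second, against 49.3% of all genes, which argues against library sets as the cause. Of the 135 with a position in the annotation 2.96% (0.813 to 7.41) lay among the 100 tested genes on either side of Ehmt2, which argues against linked alleles as the cause of all. For the part next to Ehmt2 the odds ratio was 3.05 (0.810 to 8.11; Fisher's exact p = 0.0475, 0.214 adjusted over 9 tests), and 3.54 (1.57 to 7.002; 0.00166, adjusted 0.0149) with 200 genes on either side, an interval above 1 that includes the bound of 2 set for this explanation, so linked alleles stay open there if the WT littermates lacked the floxed alleles, which is not stated, and have no reason to differ if they carried them. Of genes called the same way under both treatments 92.6% (87.1 to 96.2) were higher, but the numbers of calls alone give 86.5%, so this share decides nothing and strain background cannot be told apart from the loss of G9a by it. The loss of G9a, a repressive methyltransferase, remains a candidate explanation beside these.

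Of the 35 splits of the 8 libraries into 4 and 4, 2 called at least 155 genes, the split by genotype with 155 included, and the other called 1867, so chance cannot be excluded by this count. All further splits called 0. The split by treatment called 0 genes in edgeR and had 4096 at an unadjusted p under 0.05, and since all 35 splits call at least 0 they say nothing about treatment. The split with 1867 put WT vehicle library 1, WT CFA library 2 and both iKO CFA libraries on a side, which points to a structure of the samples.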

How the results depend on the processing

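Most alternatives were set before the data were examined. Those chosen only after the results were seen were legacy = FALSE, all libraries except WT vehicle or except WT CFA, the library set as a term without the WT vehicle libraries, the shared groups split into single libraries, and every value for genes raised in both treatments. The setting legacy = TRUE gave the same values because it is the default of the installed version. For Ehmt2, Trpa1 and Trpv1, 311 values kept direction and side of the threshold, 17 passed newly, 47 no longer passed and 6 reversed. Depth was at least 26312614 reads a library, and libraries of a group differed by more than counting error (chi-square per degree of freedom between 12.02 and 338). The cause of the changes below was not tested, except where fewer libraries were fitted.

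CFA in iKO (8 genes) gave 510 with no filter on low counts, 0 with at least 1 CPM in at least 4 libraries, 26 with limma-voom, 181 with legacy = FALSE, 8322 with only the groups compared, 0 with the replicate block, 0 with all libraries except WT vehicle and 6962 with all except WT CFA. At an unadjusted p under 0.05 it had 5791 in edgeR. DESeq2 gave 5154 for CFA in WT, 3449 for CFA in iKO, 1232 for iKO under CFA, 4133 for the interaction, 2592 for iKO averaged, 4746 for CFA averaged and 268 raised in both. For CFA in iKO, 46.1% of the DESeq2 calls were higher, against 100% in edgeR. Legacy = FALSE gave 542 for iKO under CFA. Only the groups compared gave 696 for CFA in WT, 8053 for iKO under vehicle, 62 for iKO under CFA and 37 raised in both. The replicate block gave 207 for iKO under CFA, 1062 for the interaction and 90 raised in both, though samples share only a number (correlations by number between -0.144 and 0.0275). The block also ended the list calls of granulocytes (0.0526) and red cells (0.0540) for CFA in WT and of sterol synthesis (0.0546) for CFA averaged, and changed no other list call. All libraries except WT vehicle gave 197 for iKO under CFA. With the library set as a term iKO averaged gave 1770, of which 566 were shared with the 1129, and Trpv1 reversed to -0.47 (adjusted p = 0.00116). Opposite calls of CFA in WT and iKO under CFA numbered 1091 at an unadjusted p under 0.05, and 261 and 669 with the WT CFA libraries split between the comparisons. Same calls of CFA in WT and iKO under vehicle (2074) numbered 309 and 240 with the WT vehicle libraries split. With no filter the median of all genes moved to -0.16 for CFA in WT and -0.13 for CFA averaged.

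Of 43 lists, camera with an estimated correlation called 0 in each of the 7 comparisons. Fry called 7 for CFA in WT, 0 for CFA in iKO, 9 for iKO under vehicle, 1 for iKO under CFA, 4 for the interaction, 2 for iKO averaged and 1 for CFA averaged.

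Leaving out each library in turn, with the lone library assumed to vary like the other groups, the counts ranged from 248 to 7546 for CFA in WT, 0 to 6981 for CFA in iKO, 366 to 8606 for iKO under vehicle and 65 to 5860 for iKO under CFA. They ranged from 212 to 8366 for the interaction, 303 to 5188 for iKO averaged, 29 to 8834 for CFA averaged and 41 to 556 raised in both. Ehmt2 with CFA in WT ranged from -0.19 to 0.0867 and was 0.0111 without WT vehicle library 1. Averaged over treatments, Trpa1 ranged from -0.21 to 0.13 and was 0.0467 without WT vehicle library 2, and Trpv1 ranged from -0.0123 to 0.26. None of these 3 passed in the fit to all libraries.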

Other observations

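The values below were chosen after they were seen, and no explanation was tested for them.

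Hoxd10, a homeobox gene of lumbar and sacral segments, was at 12.6 CPM in WT CFA library 1 and 2.40 CPM in WT CFA library 2. It was at 4.70 and 0.685 CPM in iKO CFA, at 1.07 and 0.536 CPM in WT vehicle and at 0.0980 and 0.144 CPM in iKO vehicle. The nuclear noncoding RNA Snhg11 was at 721 and 851 CPM in WT vehicle and between 17.7 and 32.5 CPM in the other libraries.

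Several pseudogenes took a share of the reads of the gene and pseudogene together that differed by group. Ndufs5-ps took 88.3% and 87.9% in WT CFA and at most 1.80% in the other libraries. Rps2-ps10 took 54.2% and 58.3% in WT vehicle and at most 0.607% elsewhere, and Rps18-ps5 45.5% and 45.2% against at most 0.763%. Rnps1-ps took 0.605% and 0.788% in WT CFA and between 38.8% and 67.3% in the other libraries. Rps13-ps1 took between 23.9% and 27.3% in the 4 iKO libraries and at most 1.08% in WT. Sequence reads were not analysed here.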
